A study of Mus musculus with 8 samples.

How the data were processed

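Total RNA was taken from the hippocampus of 4 homozygous Wfs1 mutant and 4 wild-type mice, depleted of ribosomal RNA, made into barcoded libraries that were pooled, and sequenced on a SOLiD 4 instrument with paired reads of 50 and 35 bp, per the labels' protocols. The authors deposited 1 table of raw counts per gene symbol for all 8 libraries, on genome build mm10 per the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation are not given in the sources used here. The unit was read from the values, which are whole numbers with a different total in each library. Each column was assigned to its animal by the title in the labels, and the number of count columns belonging to no listed sample was 0.

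The table held 24078 entries, of which 999 had no count in any library, 58 repeated the symbol of an earlier entry, 969 carried a suffix marking a duplicate, and 45 with at least 80 counts matched another entry in all libraries. All entries with a gene name were kept. Positions, exon lengths and GC content came from GENCODE release M21 on the same build, and 97.6% of entries were matched, 21436 by their current and 2060 by an older symbol, leaving 582 unmatched. Library totals ran from 3250949 to 6747411 counts. No pair of libraries agreed within sampling noise: the chi-square statistic per degree of freedom was at least 4.88 for every pair.

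Low-count genes were removed with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 20478 genes and removed 3600. Library sizes were scaled with TMM factors, and homozygous was compared with wild-type by edgeR's quasi-likelihood test (two-sided) with no covariate, since the labels give no batch, litter or sex. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. Error is given as the SD over 4 libraries for CPM and as the SE for log2 fold changes. The p-values weigh the difference between genotypes against the spread between animals within each genotype. Any difference in handling that went along with genotype is part of that difference and is not covered by them.

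A set of 29 gene lists was fixed before the data were examined, and 28 had at least 5 measured members and were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. The list of mitochondrially encoded OXPHOS genes had 0 measured of 13 members and was not tested. A list's median is given relative to the median of all genes. Lists of neighbouring tissue and other cell types were included. Some symbols stand in more than one list, such as 5 of the dopamine and noradrenaline list and 4 of the striatum list. The genes named in the text follow a rule also fixed before the data were examined: Wfs1, then the 12 genes with the largest log2 fold change in each direction among those past the threshold with a mean of at least 1 CPM and no overlap between the groups, then up to 4 members per list past the threshold by smallest p, and for lists of markers also up to 2 members of highest CPM. For marker lists the members past the threshold were limited to 2 when the rule was carried out. Some genes that the rule selects are not reported here, and the counts of named genes over alternatives leave them out, while the list tests keep them.

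The alternatives tried were size factors of DESeq2 type, library totals without TMM, no low-count filter, a filter of 1 CPM in 4 libraries, removal of ribosomal-RNA-like loci, robust dispersion, DESeq2 1.42.0, limma-voom with quality weights, 1 surrogate variable from sva 3.50.0, a threshold of 0.1, camera with an estimated correlation, fry, and leaving out each library in turn. After the data were seen, a loess curve (span 0.3) of each library's log2 counts on gene abundance, or on counts per kilobase of exon, was also removed. The edgeR code was tested on simulated counts of the same depth. In the homozygous against wild-type setting with 20285 genes, it recovered 26.9% of 67 genes changed 1.5-fold, 64.2% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, with 7 false calls (5.26% of calls). Far fewer genes were changed there than were called in the data, so these rates need not carry over. With no change simulated, 0 of 20298 genes were called. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.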

Results

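Whole-transcriptome RNA sequencing was carried out on the hippocampus of mice homozygous for a targeted mutation of Wfs1 and of wild-type mice. Wfs1 encodes wolframin, a membrane glycoprotein of the endoplasmic reticulum (ER), and loss of the human gene causes Wolfram syndrome. The series held 8 libraries, 4 per genotype, each from a different animal according to the labels. Total counts were 5021765, 3296309, 6747411 and 4873661 in wild-type replicates 7, 8, 9 and 10, and 5077114, 3250949, 3252106 and 3284625 in homozygous replicates 15, 16, 17 and 18. Spearman correlations of CPM (counts of a gene scaled to library size) across genes were 0.976 to 0.99 between wild-type libraries, 0.958 to 0.977 between homozygous libraries and 0.917 to 0.94 between genotypes, and genes are not independent replicates. The first principal component held 61.3% of the variance and placed all 4 wild-type libraries on one side and all 4 homozygous libraries on the other. The single comparison the design implies is homozygous against wild-type hippocampus, which asks which transcripts differ when Wfs1 is lost.

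Wfs1 itself was lower in every homozygous library. It was counted at 54.6, 47.5, 61.3 and 44.6 CPM in wild-type replicates 7, 8, 9 and 10, and at 16.3, 17.7, 13.3 and 12 CPM in homozygous replicates 15, 16, 17 and 18. The mean fell from 52.0 ± 7.49 to 14.8 ± 2.61 CPM (SD, n = 4 each), a log2 fold change of -1.81 (SE 0.16), with an adjusted p of 2.62e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The gene lies on the minus strand of chromosome 5, positions 36966104 to 36989205 of mm10. Counts are given per gene symbol and not per exon, so those left in homozygous libraries can include transcript outside the targeted part.

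**Figure D1:**
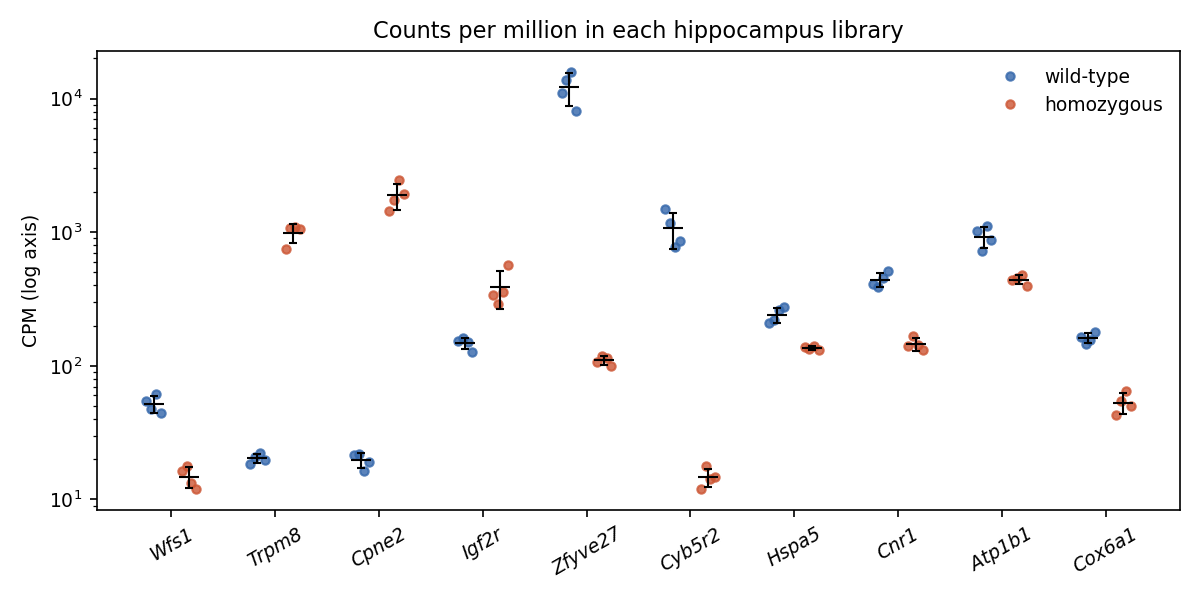
CPM (log axis) of 10 named genes in the 4 wild-type and 4 homozygous libraries; each point is a library, and the black bars give the mean and SD. Wfs1 had a mean of 52.0 CPM in wild-type and 14.8 CPM in homozygous libraries, and in none of these genes did the genotypes overlap.

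The genotypes differed over much of the transcriptome. Trpm8, a cold-activated cation channel of sensory neurons, rose from 20.3 ± 1.56 to 992 ± 165 CPM (SD, n = 4 each; log2 fold change 5.61, SE 0.19). Cpne2, a calcium-dependent phospholipid-binding copine, rose from 19.7 ± 2.55 to 1891 ± 423 CPM (log2 fold change 6.59, SE 0.24), and Tpm2, which encodes a muscle tropomyosin, from 10.2 ± 0.98 to 822 ± 325 CPM (log2 fold change 6.33, SE 0.31). In the other direction, Zfyve27, which encodes the ER-shaping protein protrudin, fell from 12187 ± 3417 to 110 ± 8.01 CPM (log2 fold change -6.79, SE 0.31). Bhlhe41, a transcription factor of the circadian clock, fell from 1878 ± 1641 to 7.44 ± 0.69 CPM (log2 fold change -7.97, SE 0.63), and Cyb5r2, a cytochrome b5 reductase, from 1075 ± 324 to 14.6 ± 2.35 CPM (log2 fold change -6.20, SE 0.27). Adjusted p was at most 1.14e-05 for these 6 genes (edgeR, Benjamini-Hochberg).

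The same rule named further genes that rose: Pm20d2, an amidohydrolase (log2 fold change 6.05, SE 0.75), Rab3b, a synaptic-vesicle GTPase (5.54, SE 0.41), the olfactory receptor gene Olfr979 (6.17, SE 0.49), Gm1968 (5.36, SE 0.39) and Mir3968 (5.40, SE 0.80). 2310050B05Rik rose as well, but from 6 counts summed over the 4 wild-type libraries to 253 in homozygous, so its fold is not given. The remaining 3, 8430422H06Rik, 3110021A11Rik and 4930523O13Rik, depended on homozygous replicate 16, and without it their log2 fold changes moved from 8.05, 5.50 and 5.63 to 5.99, 3.10 and 4.32. Leaving out wild-type replicate 8 moved 4930523O13Rik to 7.14 and Bhlhe41 to -7.19, wild-type replicate 9 moved Pm20d2 to 6.65, and Mir3968 became 6.01 without wild-type replicate 10 and 4.47 without homozygous replicate 16. Among genes that fell were Rec8, a meiotic cohesin subunit (log2 fold change -4.86, SE 0.28), Mfsd2b, a sphingolipid transporter of blood cells (-4.32, SE 0.22), Iqcf4 (-4.45, SE 0.44), Gm9159 (-5.70, SE 0.22) and the vomeronasal receptor gene Vmn1r171 (-5.52, SE 0.48). Obox2, Gm1993, Olfr239 and Mir509 also fell, but to 5, 9, 13 and 9 counts summed over the 4 homozygous libraries, from 581, 735, 627 and 223 in wild-type, so their folds are not given. Members of the Olfr, Vmn1r and Obox families have near-identical copies, and how the authors' counting shared reads between copies is not given in the sources used here. The Gm entries are of unlike kinds (Gm1968 a lincRNA, Gm9159 a processed pseudogene, Gm1993 protein-coding), and whether they have such copies was not looked at.

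Of 20478 genes tested, 4241 were higher and 4168 lower in homozygous libraries at an adjusted p of 0.05 (edgeR, Benjamini-Hochberg), and 12069 passed in neither direction. At least 8-fold changes were found for 106 higher and 46 lower genes, changes of 2-fold to 8-fold for 1402 and 812, and smaller ones for 2733 and 3310. The 4 homozygous values lay entirely above or below the 4 wild-type values for 7695 genes (37.6%), where chance gives 2.86%. With library totals alone as the scaling, 6645 genes were higher and 2412 lower, 73.4% of calls being higher against 50.4%, and the median log2 fold change of all genes moved to 0.25 from 0.05. Medians of the gene lists are therefore given below relative to the median of all genes, and other medians as fitted.

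Fold changes followed abundance. The median log2 fold change was 0.31 in the tenth of genes with the lowest mean CPM, of which 17% were higher and 3.32% lower, and -0.46 in the tenth with the highest, of which 12.6% were higher and 55.2% lower. Among protein-coding genes, the median log2 fold change of those under 1.5 kb of exon was below that of those over 5 kb in abundance deciles 3 to 10. The gap was widest in the ninth (-0.92 for 21 genes against -0.12 for 1250), and the medians were -0.86 against -0.38 in the tenth. They were 0.29 against 0.35 in the first decile and 0.27 against 0.20 in the second. Genes of receptor families with little known role in hippocampus were higher more often than lower: of 575 measured olfactory receptor genes 169 rose and 28 fell, with a median log2 fold change of 0.51, and of 146 vomeronasal receptor genes 47 rose and 5 fell, with a median of 0.42. With the abundance trend removed these medians were 0.19 and 0.15. The families were looked at after the data were seen. The shares of counts also differed: the ribosomal precursor locus Rn45s took 4.99% to 6.82% of counts in wild-type and 2.29% to 3.77% in homozygous libraries. Lars2 took 4.15% to 4.56% and 2.42% to 3.99%.

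**Figure D2:**
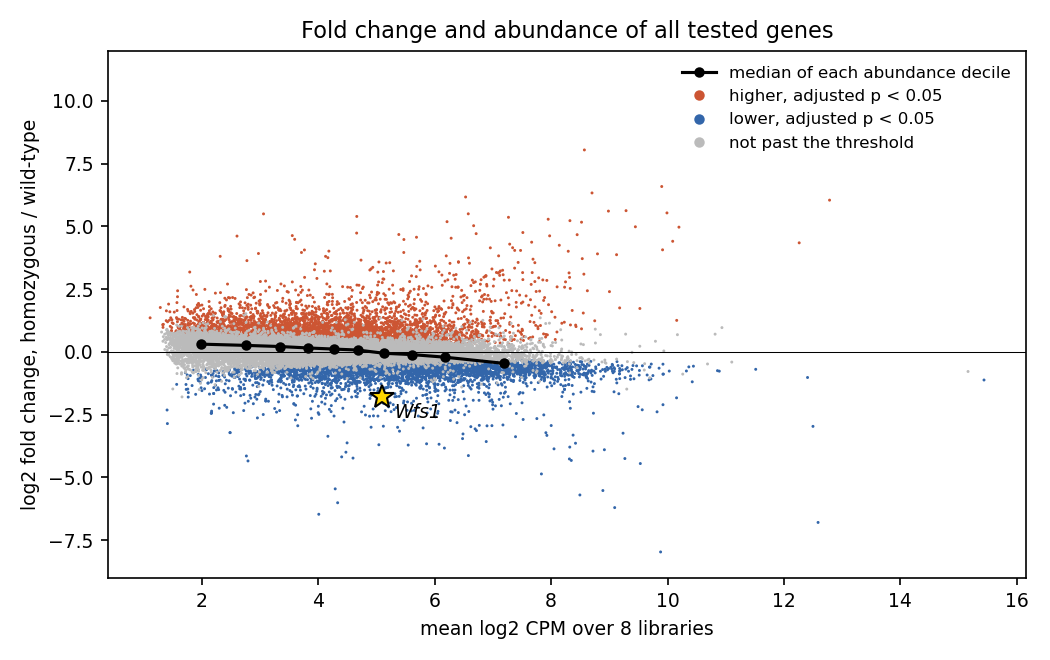
Log2 fold change of homozygous over wild-type (vertical axis) against mean log2 CPM over 8 libraries (horizontal axis) for 20478 genes; orange and blue points passed an adjusted p of 0.05, and black circles are the medians of 10 abundance deciles. The medians run from 0.31 in the scarcest genes to -0.46 in the most abundant, and Wfs1 is marked with a star.

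Nuclear-encoded subunits of mitochondrial oxidative phosphorylation (OXPHOS) fell together. Of 44 measured members 34 fell, none rose and 10 passed in neither direction, and 37 passed when adjusted over the list alone. Cox6a1 and Cox8a, subunits of cytochrome c oxidase, fell from 161 ± 13.6 to 53.0 ± 9.20 CPM (log2 fold change -1.61, SE 0.15) and from 133 ± 9.78 to 44.6 ± 8.44 CPM (-1.58, SE 0.15). Atp5d of the ATP synthase (log2 fold change -1.55, SE 0.15) and Cyc1 of complex III (-1.16, SE 0.12) fell as well. The median of the list was -0.86 relative to all genes, with an adjusted p of 1.16e-13 in limma's camera with a preset correlation of 0.01, and an adjusted p = 0.116 with an estimated correlation. It stayed called when a trend of fold change on abundance was removed (median -0.72, adjusted p 3.42e-10 in camera on the edgeR fit) and when a trend on counts per kilobase of exon was removed (median -0.34, adjusted p 0.0221). In the latter 16 members fell and 4 rose, and Cox6a1 and Cox8a were -0.78 and -0.76.

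Sodium-potassium and proton pumps also fell, 11 of 16 measured members being lower, none higher and 13 past the threshold when adjusted over the list alone. Atp6v0c, the membrane ring subunit of the vacuolar proton pump, went from 442 ± 71.7 to 157 ± 10.2 CPM (log2 fold change -1.49, SE 0.15). Atp1b1, the sodium pump beta subunit, went from 928 ± 170 to 442 ± 33.3 CPM (log2 fold change -1.07, SE 0.17), while Atp6v1b2 fell with -1.10 (SE 0.14). The list median was -0.69 relative to all genes (adjusted p 0.000811 in limma's camera, adjusted p = 0.282 with an estimated correlation). Pump transcripts were abundant, and with the abundance trend removed the list was no longer called (adjusted p 0.351 in camera), nor was Atp1b1 (-0.32, adjusted p 0.0745 in edgeR). The list was not called with the density trend removed either (counts per kilobase of exon; adjusted p 0.53 in camera). Atp6v0c stayed called with the abundance trend (-0.94, adjusted p 0.000297 in edgeR) and with the density trend removed (-0.73, adjusted p 0.00129). So did Atp6v1b2 (-0.52, adjusted p 0.0115 in edgeR, and -0.40, adjusted p 0.0451).

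Genes of glutamatergic synapses and of GABAergic neurons fell more often than they rose. In the glutamatergic list 18 of 28 measured members fell and none rose, with 20 past the threshold adjusted over the list alone, among them the NMDA receptor subunit gene Grin2c (log2 fold change -1.52, SE 0.19), the scaffold gene Dlg4 (-0.97, SE 0.15), the vesicular transporter gene Slc17a7 (-0.92, SE 0.17) and Grm7 (-0.63, SE 0.13). Among GABAergic neuron genes 14 of 25 fell and 2 rose, with 17 past the threshold adjusted over the list alone. Cnr1, the cannabinoid receptor carried by a class of interneurons, fell from 441 ± 53.6 to 145 ± 16.2 CPM (log2 fold change -1.60, SE 0.15), and Cck fell with -0.90. CA1 pyramidal markers fell in 7 of 13 members with none higher, 7 being past the threshold adjusted over the list alone, including Fibcd1 (-0.71, SE 0.15), Nr3c2 (-0.87, SE 0.20), Mpped1 (-0.73, SE 0.13) and Man1a (-0.75, SE 0.14). The list medians were -0.55, -0.44 and -0.70 relative to all genes, with adjusted p of 0.000536, 0.00301 and 0.0162 in limma's camera. With an estimated correlation none of the 3 was called (adjusted p = 0.282, 0.221 and 0.282), and none was with the abundance trend removed (adjusted p 0.462, 0.172 and 0.179 in camera) or the density trend removed (adjusted p 0.154, 0.45 and 0.18). Some single calls ended too: Slc17a7 was -0.13 (adjusted p 0.463 in edgeR) and Dlg4 -0.30 (adjusted p 0.0852) with the abundance trend removed. In that setting Grin2c (-1.35, adjusted p 0.000377) and Grm7 (-0.51, adjusted p 0.0109) stayed called. With the density trend removed Slc17a7 was -0.07 (adjusted p 0.728), Cck -0.12 (adjusted p 0.521) and Fibcd1 -0.27 (adjusted p 0.178).

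CA2 and CA3 markers and dentate granule markers were not called as lists (adjusted p 0.372 and 0.368 in limma's camera). Of 13 CA2 and CA3 members 1 rose, the neurotrophin gene Ntf3 (log2 fold change 1.27, SE 0.23), and 5 fell, among them Bok (-1.01, SE 0.19) and Cpne4 (-0.54, SE 0.13), while Pvrl3 passed in neither direction (0.28, SE 0.18), with 6 past the threshold adjusted over the list alone. Of 14 dentate granule members only Glis3 passed in the edgeR fit (-0.64, SE 0.17), both over all genes and adjusted over the list alone, where the count was 1. C1ql3 (-0.35, SE 0.14) and Pdzd2 (0.27, SE 0.12) did not. Cpne4 did not pass with the abundance trend removed (-0.20) or the density trend removed (-0.10), and neither Cpne4 (-0.34) nor Glis3 (-0.44) did with library totals as the only scaling. Glis3 lay in both genotypes, per kilobase of exon, within the range given below for 137 keratin, taste receptor, cytochrome P450 2 and Mrgpr genes.

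Genes of ER stress and the unfolded protein response went both ways. Of 30 measured members 12 fell, 4 rose and 14 passed in neither direction, with 18 past the threshold adjusted over the list alone. Hspa5, the ER chaperone BiP, fell from 241 ± 31.0 to 136 ± 4.45 CPM (SD, n = 4 each; log2 fold change -0.83, SE 0.13), and Asns, asparagine synthetase, from 73.3 ± 6.41 to 42.7 ± 6.17 CPM (-0.78, SE 0.13). Ern1, the ER stress sensor IRE1, rose from 18.1 ± 2.36 to 34.4 ± 4.35 CPM (0.94, SE 0.15), and the stress-induced sestrin gene Sesn2 from 460 ± 351 to 9361 ± 7319 CPM (4.35, SE 0.66). Sesn2 was 4.96 without wild-type replicate 8 and 3.64 without homozygous replicate 18. Ern1 stayed called with the density trend removed (0.76, adjusted p 0.00238 in edgeR). Per kilobase of its 8173 bp of exon, Ern1 lay in both genotypes within the range of 137 keratin, taste receptor, cytochrome P450 2 and Mrgpr genes. That range, from the 10th to the 90th percentile, was 1.70 to 7.61 CPM in wild-type and 2.19 to 8.40 in homozygous libraries. It was chosen after the data were seen. The list as a whole was not called (median -0.41 relative to all genes, adjusted p 0.181 in limma's camera). With the abundance trend removed Hspa5 (-0.38, adjusted p 0.0405 in edgeR) and Asns (-0.65, adjusted p 0.00345) stayed called. With the trend on counts per kilobase removed Hspa5 (-0.20, adjusted p 0.26 in edgeR) and Asns (-0.38, adjusted p 0.0517) no longer passed.

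Among ER calcium handling genes 7 of 23 fell, 2 rose and 14 passed in neither direction, with 9 past the threshold adjusted over the list alone. Those that fell included the calmodulin gene Calm3, from 1122 ± 103 to 519 ± 37.0 CPM (log2 fold change -1.11, SE 0.15), the calcium sensor gene Ncs1 (-0.96, SE 0.15), the ER calcium pump gene Atp2a2 (-0.83, SE 0.15) and Tmbim6 (-0.82, SE 0.15). The list was not called (median -0.21, adjusted p 0.204 in limma's camera). With the abundance trend removed its median was 0.17 (adjusted p 0.857) and neither Calm3 (-0.33, adjusted p 0.0544 in edgeR) nor Atp2a2 (-0.28, adjusted p 0.139) passed. In that setting Ncs1 (-0.48, adjusted p 0.0107 in edgeR) and Tmbim6 (-0.45, adjusted p 0.0171) stayed called. With the density trend removed none of Calm3 (-0.22), Ncs1 (-0.32), Atp2a2 (-0.18) and Tmbim6 (-0.28) passed.

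Several genes of insulin-like growth factor signalling and the insulin receptor gene were higher. Igf2r rose from 148 ± 14.4 to 387 ± 123 CPM (log2 fold change 1.38, SE 0.20), Igf1 from 67.3 ± 4.14 to 147 ± 45.4 CPM (1.13, SE 0.19), Igf1r with 0.51 (SE 0.12) and Insr with 0.50 (SE 0.12). In the list 6 of 19 members rose and 4 fell, 11 passing when adjusted over the list alone, and the list was not called (adjusted p 0.628 in limma's camera, which gave a higher direction while the median was -0.0004 relative to all genes). Dopamine and noradrenaline signalling had 6 of 21 members higher and 3 lower, 10 past the threshold adjusted over the list alone, with no call (median 0.16, adjusted p 0.522 in camera). The D1-class receptor genes moved apart: Drd5 fell from 160 ± 31.8 to 31.0 ± 15.4 CPM (-2.37, SE 0.28), and Drd1a rose from 22.6 ± 0.59 to 52.7 ± 11.7 CPM (1.22, SE 0.16). Th, the rate-limiting enzyme of catecholamine synthesis, rose from 4.89 ± 0.90 to 23.9 ± 14.0 CPM (2.26, SE 0.36), and Adra1d fell (-1.01, SE 0.15).

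Activity-regulated immediate early genes had 4 of 21 members higher and 6 lower, 10 past the threshold adjusted over the list alone, and were not called (median -0.06, adjusted p 0.793 in limma's camera). Fosb rose (log2 fold change 1.10, SE 0.14) and Egr1 rose (0.52, SE 0.12), while Fos (-0.83, SE 0.17) and Dusp6 (-0.69, SE 0.13) fell. Interferon response and antigen presentation genes had 7 of 22 members higher and 6 lower, 15 past the threshold adjusted over the list alone, with no call (median -0.06, adjusted p 0.849 in camera). The class I light chain gene B2m fell (-1.38, SE 0.19), as did Tapbp (-3.57, SE 0.65, and -2.40 without wild-type replicate 8), and Isg15 (0.99, SE 0.25) rose. Dusp6 did not pass with the density trend removed (-0.30), nor Isg15 with the abundance trend removed (0.70). Isg15 lay in both genotypes, per kilobase of exon, within the range given above for 137 keratin, taste receptor, cytochrome P450 2 and Mrgpr genes.

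**Figure D3:**
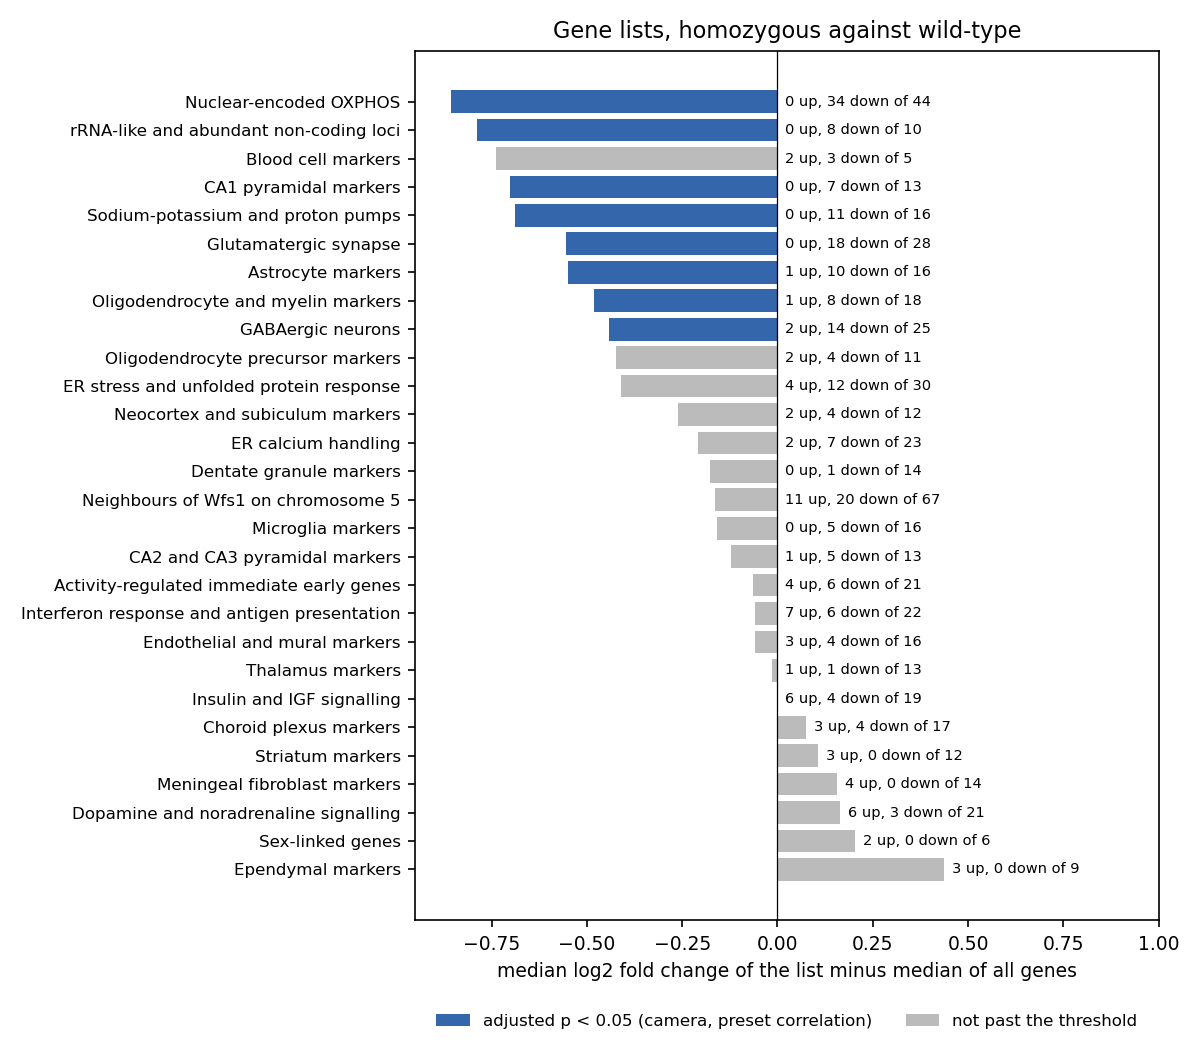
Median log2 fold change of each of 28 gene lists minus the median of all genes (horizontal axis), with the number of members higher (up) and lower (down) at an adjusted p of 0.05 in edgeR beside each bar. Blue bars are the 8 lists called by camera with a preset correlation of 0.01, all of them lower, and grey bars are the other 20. With an estimated correlation 0 lists were called (lowest adjusted p = 0.116).

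Astrocyte markers fell in 10 of 16 members and rose in 1, with 11 past the threshold adjusted over the list alone. They included the glutamate transporter genes Slc1a2, from 2325 ± 287 to 1386 ± 118 CPM (log2 fold change -0.75, SE 0.17), and Slc1a3 (-0.68, SE 0.16), together with Fgfr3 (-1.0, SE 0.13) and Ntsr2 (-1.0, SE 0.18). Oligodendrocyte and myelin markers fell in 8 of 18 members and rose in 1, with 11 past the threshold adjusted over the list alone. Mbp fell from 768 ± 203 to 477 ± 37.1 CPM (-0.69, SE 0.19), and Cldn11 with -1.05 (SE 0.17). The medians were -0.55 and -0.48 relative to all genes, with adjusted p of 0.0264 and 0.0434 in limma's camera, and with an estimated correlation adjusted p = 0.282 and 0.57. Both calls ended with the abundance trend removed, where Slc1a2 (0.21) and Mbp (0.06) turned and Slc1a3 was -0.05, and without wild-type replicate 7 (adjusted p 0.0642 and 0.114 in camera). With the density trend removed the astrocyte median turned to 0.07 (adjusted p 0.853 in camera) and the oligodendrocyte median was -0.13 (adjusted p 0.571). There Slc1a2 (0.10) and Mbp (0.07) turned and Slc1a3 was -0.04. The oligodendrocyte call also ended without wild-type replicate 8 (adjusted p 0.0588) and without homozygous replicate 18 (adjusted p 0.142).

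Other cell type markers gave no list call. Oligodendrocyte precursor markers had 2 of 11 higher and 4 lower (9 adjusted over the list alone; median -0.42, mean log2 fold change 0.04, adjusted p 0.488 in limma's camera), with Olig1 (-0.89, SE 0.16) and Bcas1 (-0.71, SE 0.15) lower and Cspg4 higher (2.53, SE 0.73, and 1.38 without homozygous replicate 16). Microglia markers had 5 of 16 lower and none higher (5 adjusted over the list alone; median -0.16, adjusted p 0.278 in camera), including Ctss (-0.88, SE 0.16) and C1qa (-0.63, SE 0.18), while Csf1r did not pass (0.44, SE 0.25). Endothelial and mural markers had 3 of 16 higher and 4 lower (8 adjusted over the list alone; median -0.06, adjusted p 0.714 in camera), with Pdgfrb lower (-0.99, SE 0.14), Abcc9 higher (0.52, SE 0.12) and Slco1c1 in neither (-0.41, SE 0.16). Blood cell markers had 2 of 5 higher, one of them Alas2 (0.91, SE 0.25), and 3 lower (5 adjusted over the list alone; median -0.74, adjusted p 0.522 in camera), but Hbb-b1 and Hbb-b2 (-1.95, SE 0.40) held identical counts in every library and are one measurement. The third member that fell was Beta-s (-0.69, SE 0.18). With the density trend removed Bcas1 (-0.24), Ctss (-0.46), C1qa (-0.50) and Beta-s (-0.13) did not pass. With library totals only C1qa (-0.42) and Beta-s (-0.49) did not. With robust dispersion Cspg4 did not (adjusted p 0.0757 in edgeR). Per kilobase of exon, Abcc9 lay in both genotypes within the range given above for 137 keratin, taste receptor, cytochrome P450 2 and Mrgpr genes.

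Markers of tissue that borders the hippocampus were also measured. Choroid plexus markers had 3 of 17 higher and 4 lower (7 adjusted over the list alone; median 0.07, adjusted p 0.944 in limma's camera, which gave a lower direction), with Tmem72 higher (2.57, SE 0.37), Sostdc1 lower (-2.42, SE 0.23) and Enpp2 lower (-2.31, SE 0.60, and -1.58 without wild-type replicate 8). Enpp2 did not pass with the abundance trend removed (-1.71), with the density trend removed (-1.61) or with robust dispersion. Ttr, the choroid plexus transthyretin gene, had 464 ± 396 CPM in wild-type and 341 ± 370 CPM in homozygous libraries and did not pass (-0.44, SE 0.98). Ependymal markers had 3 of 9 higher and none lower (3 adjusted over the list alone; median 0.44, adjusted p 0.368 in camera), including Spag17 (1.02, SE 0.18) and Rarres2 (1.26, SE 0.33), with Foxj1 in neither (0.64, SE 0.37). Meningeal fibroblast markers had 4 of 14 higher and none lower (4 adjusted over the list alone; median 0.16, adjusted p 0.302 in camera), with Col1a1 (0.88, SE 0.15), Col1a2 (0.75, SE 0.17) and Fmod (0.67, SE 0.15) higher and Slc13a4 in neither (0.06, SE 0.21). Neocortex and subiculum markers had 2 of 12 higher, Foxp2 (0.77, SE 0.12) and Rorb (1.65, SE 0.26), and 4 lower, including Tle4 (-0.81, SE 0.10), with 6 adjusted over the list alone (median -0.26, adjusted p 0.477 in camera). Thalamus markers had 1 of 13 higher, Ramp3 (1.27, SE 0.25), and 1 lower, Shox2 (-0.81, SE 0.21), with 2 adjusted over the list alone (median -0.02, adjusted p 0.821 in camera, which gave a higher direction), and Plekhg1 (0.20, SE 0.18) and Ntng1 (-0.22, SE 0.13) in neither. Striatum markers had 3 of 12 higher, including Gpr6 (1.03, SE 0.26), and none lower (3 adjusted over the list alone; median 0.11, adjusted p 0.459 in camera), with Pde10a (-0.27, SE 0.12) and Rgs9 (-0.45, SE 0.31) in neither. Per kilobase of exon, Spag17, Col1a1, Col1a2, Fmod, Foxp2 and Gpr6 lay in both genotypes within the range given above. That range is of 137 keratin, taste receptor, cytochrome P450 2 and Mrgpr genes.

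The remaining lists covered abundant non-coding loci and sex chromosomes. Ribosomal-RNA-like and abundant non-coding loci fell in 8 of 10 members with none higher (9 adjusted over the list alone; median -0.79, adjusted p 0.0015 in limma's camera, adjusted p = 0.116 with an estimated correlation). Rn45s fell from 60760 ± 10462 to 27996 ± 6215 CPM (-1.12, SE 0.31), Rmrp from 639 ± 105 to 213 ± 54.4 CPM (-1.58, SE 0.21) and Rian with -0.84 (SE 0.15), while Lars2 did not pass (-0.78, SE 0.29). With the abundance trend removed the list was not called (adjusted p 0.764 in camera), Rn45s (0.26) and Lars2 (0.60) turned, and Rian (-0.25) did not pass. With the density trend removed the list was not called (adjusted p 0.53 in camera) and Lars2 (0.27) turned. Sex-linked genes had 2 of 6 higher, Eif2s3y (2.60, SE 0.36) and Kdm5d (0.69, SE 0.12), and none lower (2 adjusted over the list alone; median 0.20, adjusted p 0.267 in camera). Per kilobase of exon, Kdm5d lay in both genotypes within the range given above for 137 keratin, taste receptor, cytochrome P450 2 and Mrgpr genes. Eif2s3y (5.15 CPM in wild-type over 4161 bp of exon) lay below that range in wild-type and within it in homozygous libraries. Xist (-0.11, SE 0.14) and Uty (0.40, SE 0.25) passed in neither direction and were counted in every library. In both genotypes Uty lay within that range per kilobase of exon and Xist above it. The sex of the animals is not given in the sources used here.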

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

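The rule for single libraries far from their group was fixed before the data were examined, while every test of an explanation in this part was set down after the result it bears on had been seen.

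Among 266 groups of 4 values, 17 had a library whose gap to its nearest neighbour was a larger part of the group's range than Dixon's 95% critical value for 4 values, where chance gives about 1 in 20 groups, or 13.3. Wild-type replicate 8 stood apart for 6 genes: 4930523O13Rik (77.3 CPM against 5.57 to 13.3 in the other wild-type libraries), Tapbp (591 against 64.9 to 138), Rgs9 (177 against 61.4 to 71.1), Tmem72 (34.2 against 19.9 to 22.3), Enpp2 (2784 against 590 to 958) and Rarres2 (14.2 against 10.3 to 10.9). Homozygous replicate 16 stood apart for 8430422H06Rik (2487 CPM against 36.7 to 295 in the other homozygous libraries) and 3110021A11Rik (646 against 23.2 to 55.3). Homozygous replicate 17 stood apart for Drd5 (54.1 CPM against 22.6 to 23.8), Cck (102 against 80.4 to 83.9) and Lars2 (37560 against 23280 to 23760). Homozygous replicate 18 stood apart for Gm1968 (575 CPM against 198 to 230), Bcas1 (59.0 against 76.9 to 80.2) and Mrfap1 (108 against 91.9 to 94.6). Homozygous replicate 15 stood apart for Trpm8 (747 CPM against 1051 to 1100), for Obox2 (0.353 against 0.289 to 0.294, which is 1 or 2 counts) and for its total of 5077114 counts, against 3250949 to 3284625 in the others.

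Abundant transcripts were lower and scarce ones higher in homozygous libraries, and short, abundant mRNAs fell most. If only homozygous libraries held additional reads spread evenly over all exons, the slope of fold change on exon length would be steepest in scarce genes. The slope was 0.035 in the 5 lower and 0.118 in the 5 upper abundance deciles, a difference of -0.0834 (95% interval -0.117 to -0.053). But 137 keratin, taste receptor, cytochrome P450 2 and Mrgpr genes had a median of 3.39 CPM per kilobase of exon in wild-type and 4.14 in homozygous libraries. With such reads in both genotypes the slope could flatten in scarce genes, so the test cannot decide. A difference in depth is argued against: the gap between bottom and top decile differed between genotypes by 0.489 among libraries under 4000000 counts and by 0.808 among deeper ones, against 0.682 in all, although the first rests on a single wild-type library and the second on a single homozygous one. Within each quintile of GC content the gap between bottom and top decile was at least 0.674, against 0.764 over all genes, so GC content as annotated is not the whole cause. What stays open is additional reads spread over exons, or a difference in RNA quality, fragment length or ribosomal depletion that went along with genotype. An effect of genotype stays open too, and was not tested apart from these.

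OXPHOS transcripts were lower in homozygous libraries, and their median exon length was 1.92 kb, against 3.96 kb for other protein-coding genes. With the abundance trend removed the list median was still -0.72 relative to all genes. Measured against genes matched on exon length and CPM, the list median per library was 0.216 ± 0.059 in wild-type and -0.066 ± 0.07 in homozygous libraries (SD, n = 4 each), a difference of -0.28 with no overlap (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 can give). The matched genes themselves had a median log2 fold change of -0.55 over 10000 random lists, against -0.80 for OXPHOS, both as fitted and not relative to all genes. Much of the fall is therefore shared with other short, abundant mRNAs. The rest may be a change in OXPHOS transcripts that goes with genotype, a hypothesis that stays open together with a sharper effect of transcript length than the matching covers.

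Changes of at least 8-fold were found for 152 genes, of which 12, such as Olfr979 and Vmn1r171, encode olfactory or vomeronasal receptors. The 20478 genes tested held 575 olfactory and 146 vomeronasal receptor genes annotated as protein-coding. By name, 31 of the 152 were Gm, Rik or LOC models, 8 were microRNAs or small nucleolar RNAs and 101 were other genes. The shares of these kinds over all genes were not counted. A single aberrant library is argued against as the source of the calls, since at least 150 of the 152 stayed called in the same direction whichever library was left out. Their size was less steady. From 131 (without homozygous replicate 16) to 147 (without wild-type replicate 9) stayed at least 8-fold. Sequence carried along beside the targeted Wfs1 allele is argued against as the site of these genes: 0 of the 147 with a known position lay within 10 Mb of Wfs1. That count does not cover sequence carried along outside this window. For the genes that rose, the median coefficient of variation was 58.6% among homozygous and 17% among wild-type libraries, and for those that fell 27.3% and 39.1%, against 13.9% and 10.8% for other genes of the upper abundance deciles. These other genes were not matched to the 152 on counts. In the genotype where a gene was low its counts could be few, as for Obox2 with 5 over the homozygous libraries. Sampling noise then adds to its coefficient. What stays open is an effect of genotype, sequence carried along outside that window and any difference in handling that went along with genotype. The labels, which say that libraries were pooled for sequencing, give no preparation date, and none of these was tested.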

How the results depend on the processing

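Removal of the abundance or density trend was chosen after seeing the data, and the other alternatives here were planned. Gene counts kept within 1.5 times of 4241 higher and 4168 lower except with library totals as the only scaling (6645 and 2412, a shift of the median by construction), and with one library left out they ran from 3178 to 3995 and from 3311 to 4253. Of the 8409 calls, 6067 remained in the same direction with the abundance trend removed and 5429 of the 8258 testable with the density trend removed, where 2 others were called in the opposite direction. Wfs1 stayed called throughout, from -1.60 to -1.85 over settings and from -1.72 to -1.90 with one library left out. Of 28 lists, 8 were called in the planned fit, 6 to 8 with one library left out, 1 with the abundance trend removed, 1 with the density trend removed, 0 with an estimated correlation in camera (3 at an unadjusted p under 0.05) and 20 by fry, which does not compare a list with other genes; the cause was not tested. The odds ratio for calls near Wfs1 was 1.11, and it turned to 0.936 with library totals only (1.05 to 1.19 with one library left out); the cause was not tested.

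Of 107 reported named genes past the threshold (Wfs1 aside), 93 stayed called with the abundance trend removed, 10 lost the call and 4 turned, and of 102 testable with the density trend removed 81 stayed, 19 lost it and 2 turned. Turned with the abundance trend removed were C1ql3 (0.0819), Pde10a (0.0186), Ttr (0.00483), Slc1a2 (0.21), Mbp (0.0553), Rn45s (0.26), Lars2 (0.60), Xist (0.37), Htt (0.0273), and the medians of the ER calcium (0.17), choroid plexus (-0.0078), insulin (0.31), thalamus (0.0889) and endothelial (0.0022) lists. Turned with the density trend removed were C1ql3 (0.38), Ttr (0.39), Slc1a2 (0.10), Mbp (0.0676), Lars2 (0.27), Xist (0.0704), and the medians of the astrocyte (0.0704), striatum (-0.000551) and insulin (0.46) lists. Xist was 0.0896 with library totals only, the insulin list 0.000553 with DESeq2-type factors and the blood cell list 0.58 with no filter. With each library left out in turn, Rgs9 (-0.61 to 0.0237), Ttr (-1.11 to 0.27), Slc13a4 (-0.11 to 0.20) and the choroid plexus (-0.17 to 0.21), insulin (-0.0621 to 0.0604), interferon (-0.10 to 0.0940) and thalamus (-0.0840 to 0.0853) lists turned, and none of these was called before. The cause was not tested beyond what each setting removes.

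No paired analysis was possible because the replicate numbers of the genotypes, 7 to 10 and 15 to 18, are not shared.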

Other observations

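The window around Wfs1 and its list were planned, while the counting of splits, set out beforehand as a check, had its prediction written only after its result, and the comparison of Wfs1 with gene families was chosen after the data were seen.

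Genes beside Wfs1 on chromosome 5 included several that fell. Mrfap1 fell from 207 ± 12.3 to 96.8 ± 7.79 CPM (SD, n = 4 each; log2 fold change -1.10, SE 0.12), Ppp2r2c, a phosphatase regulatory subunit, from 335 ± 51.4 to 181 ± 7.35 CPM (-0.89, SE 0.14), and Htt, the huntingtin gene, from 290 ± 37.9 to 205 ± 13.0 CPM (-0.50, SE 0.14). Htt turned to 0.03 with the abundance trend removed and did not pass with library totals only (-0.30), and Ppp2r2c did not pass with the density trend removed (-0.19). Drd5 lies in the same region. Of 67 measured genes in the neighbour list 11 rose and 20 fell, 32 passing when adjusted over the list alone, and the list was not called (median -0.16, adjusted p 0.206 in limma's camera). Within 10 Mb of Wfs1, 43.7% of 174 genes were called against 41.1% of other genes, an odds ratio of 1.11 (95% interval 0.812 to 1.52; Fisher's exact test, two-sided p = 0.487), and the odds ratio was 1.14 within 5 Mb, 1.002 within 20 Mb and 1.23 for the list.

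Among 35 ways to split the 8 libraries into 4 and 4, only 1, the real one, called as many genes higher (4241) or lower (4168), and the highest of the others called 1. Chance is argued against for the gene counts at 1 in 35, the smallest share these splits can give, but is not excluded. The other splits mix the genotypes, so they carry the difference between them as spread, which lowers their counts. For lists chance is not argued against: 5 of the 35 splits called 8 or more, and the highest of the others called 9. The other 4 of these 5 hold 3 homozygous libraries on one side, so they keep part of the genotype contrast, and the 18 splits with 2 on each side called at most 4.

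Wfs1 counts left in homozygous libraries came to 3.91 CPM per kilobase of exon, against 13.7 in wild-type. For 137 keratin, taste receptor, cytochrome P450 2 and Mrgpr genes the homozygous values had a median of 4.14 and a range from the 10th to the 90th percentile of 2.19 to 8.40, and in wild-type a median of 3.39. Over all 871 genes of 7 families, with olfactory and vomeronasal receptors and beta-defensins added, the homozygous median was 1.85 (0.61 to 6.58), and 21.7% lay at or above Wfs1. The medians of olfactory and vomeronasal receptor genes alone were 1.63 and 0.908. Whether the counts left are reads of the kind found over genes with little transcript in brain or transcript from outside the targeted part stays open, because neither was separated.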
